A study of Mus musculus with 6 samples.

How the data were processed

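Gene expression was measured in B16 melanomas, tumors of a transplantable mouse melanoma cell line, grown in syngeneic C57BL/6 mice. Per the labels' protocols, mice received 400000 cells, and tumors taken at day 8 were sorted by area into large (70 to 80 mm2) and small (10 to 20 mm2). The labels also state that tumors were trimmed of adjacent normal tissue, and that 100 ng of total RNA was amplified in a repeated linear procedure before biotin labelling. There were 6 samples with 1 array each, 3 from large and 3 from small tumors. The labels number the replicates 1 to 3 in each group but say nothing further on how many mice or inoculation batches they came from, so p-values measure the spread between these samples.

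The deposited signal values are intensity, the mean bead brightness of each probe on a linear scale, per the file headers, and were read from Illumina bead arrays with GenomeStudio per the submitters' processing notes. The version and settings are not given in the sources used here. The lowest intensity on an array lay between 84.2 and 98.4, so no background had been subtracted. A detection p-value for each probe and array was deposited with the signals, per the file headers. A second deposited table holds the authors' processed intensity for part of the probes. It is on a linear scale with a lower bound of 28.8 on every array, and its column medians were 132.7, 130.8 and 128.5 in large and 119.99, 130.2 and 131.6 in small tumors for replicates 1 to 3. Each of its columns correlated best with the signals of its own array (r at least 0.953 across genes after centring each gene, against at most 0.51 with another array). Its background correction and normalization stayed unknown, because its values were not a strictly rising function of the signals (Spearman's rho 0.993 to 0.997 across probes). It was used as an alternative.

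Signals were background-corrected, quantile-normalized and log2-transformed with neqc of limma 3.58.1 in R 4.3.3, with the background inferred from the detection p-values and an offset of 16. Probes with a detection p-value under 0.05 on at least 3 of the 6 arrays were kept, which left 19120. Gene names came from the array platform's annotation, which was at hand only for probes of the authors' processed table. The authors' table holds 20346 of the 45281 probes on the array. Of these 20346, 17300 had 1 symbol, 11 had several and 3035 were unnamed here. Entrez identifiers of 17278 probes matched a RefSeq gene table of assembly GRCm38.p6, 33 did not, and 0 symbols changed. That table was used for names only, and no genomic coordinates are given. Of the kept probes, 16256 had a single symbol. For each gene the probe with the highest mean log2 value over all 6 arrays was used, which gave 10523 genes, of which 3967 had several detected probes. The 2864 kept probes without a single symbol were left out of the gene test. As a check for arrays deposited more than once, signals were compared as deposited without rounding, and the highest share of probes with exactly equal signals in any pair of arrays was 0%.

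Large and small tumors were compared gene by gene with lmFit and eBayes of limma, with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05. Log2 fold changes are large minus small, with the standard error (SE) of the fit. For a gene not detected on any array of 1 group, the fold is given as a lower bound against the lowest signal among detected probes. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, in each case adjusted over 35 lists with at least 5 tested members. Members were also counted after adjustment over the list alone. The lists covered the interleukin-1 family and its inflammatory targets, interferon responses, antigen presentation, chemokines, checkpoint genes, tumor cell programs, and markers of the immune, stromal, skin, muscle, fat, nerve and blood cells that a tumor sample can hold.

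Groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 15 genes with the largest rise and the 15 with the largest fall among called genes whose groups did not overlap, the interleukin-1 genes, and the 4 members with the smallest p of each list that was called or held a called gene, or 2 of any other list. A comparison of single values of 3 against 3 has a smallest exact permutation p of 0.1. The alternatives were 4 other normalizations, the authors' processed table, 3 filters on dim probes, 2 other rules from probes to genes, a trended and robust prior, array weights, the replicate number as a block and omission of each array in turn. Models with the mean level of the keratinocyte or the skeletal muscle list as a covariate were added after seeing the data.

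The gene test was tested on simulated data for the comparison of large with small tumors, with 200 of 10523 genes changed. It recovered 81.5% of them at a log2 change of 1 with 9 false calls, and 99% at a log2 change of 2 with 11 false calls. The simulated noise was independent between genes. On the real arrays genes varied together, with 63.1% of the within-group variance on 1 axis, so these figures need not hold there. The number of arrays limits the precision. The median standard deviation (SD) of a gene between replicates was 0.15 in large and 0.18 in small tumors on the log2 scale. Il1a, the gene of interleukin-1 alpha, had no probe among those named here and is not analysed. Probes outside the authors' processed table could not be named, so this does not show that the array lacks Il1a.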

Results

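The series compared gene expression of large and small B16 melanomas taken on the same day, and its title names interleukin-1 alpha and resistance to immunotherapy. The median signal of an array was 117 to 128 in the 3 large tumors and 104 to 115 in the 3 small tumors. Small replicate 1 was the dimmest array, with a 95th percentile of signal of 949 against 1477 to 1997 on the other arrays, and 17310 probes detected against 18331 to 19771.

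Large tumors held less RNA of interferon-induced, antigen presentation, T cell, NK cell and skeletal muscle genes than small tumors, by camera at a preset correlation. No list was called with an estimated correlation (adjusted p = 0.286 to 0.295 for these lists). Cxcl9 (probe ILMN_1215862), an interferon-induced chemokine that attracts T cells, fell by 2.70 ± 0.49 (SE, n = 3 per group) on the log2 scale, which is 6.49-fold. Gbp2, an interferon-induced guanylate-binding protein, fell by 2.67 ± 0.35, and Psmb9, a subunit of the immunoproteasome that makes peptides for MHC class I, fell by 2.49 ± 0.26. Ckm, the creatine kinase of muscle, fell by 2.39 ± 0.20. The rises of called genes were led by Cdh19, a cadherin of the neural crest and Schwann cell lineage, which rose by 1.44 ± 0.22 (2.72-fold).

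Of 10523 genes, 260 were called, 83 higher and 177 lower in large tumors. At least 2-fold changes made up 10 of the rises and 139 of the falls. With quantile normalization and no background correction, 176 genes were higher and 224 lower. In all 260 genes the groups did not overlap, as in 29.6% of all genes tested, where chance gives 10%. At an unadjusted p under 0.05 there were 2371 genes, 1298 of them higher. The count of called genes changed widely with the array left out. It was 0 without large replicate 1 or without large replicate 3, 29 without large replicate 2, 85 without small replicate 1 and 1 without small replicate 3 (limma), while 2303, 1591, 1644, 1876 and 1860 genes had an unadjusted p under 0.05 in these fits. Without small replicate 2 it was 300, 77 higher and 223 lower. All 260 genes kept their sign whichever array was left out, which had to be so because their groups did not overlap.

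Among the largest falls of called genes were further interferon-induced GTPases. Ifi47 fell by 2.53 ± 0.34, and Gbp3, Gbp7 and Irgm2 had log2 fold changes of -2.20 ± 0.31, -2.20 ± 0.35 and -2.19 ± 0.38. Apol9a and Apol9b, apolipoprotein L genes, fell by 2.55 ± 0.23 and 2.37 ± 0.40, and Batf2, a transcription factor, fell by 2.08 ± 0.24. The other large falls were muscle genes. Pvalb, the calcium buffer parvalbumin of fast fibres, fell by 2.62 ± 0.30, Myh4, a fast myosin heavy chain, by 2.31 ± 0.30, Tcap, a titin-binding protein, by 2.30 ± 0.26, and Tnnt3, fast troponin T, fell by 2.20 ± 0.17. Adjusted p-values of these 15 largest falls lay between 0.0161 and 0.0456.

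**Figure D1:**
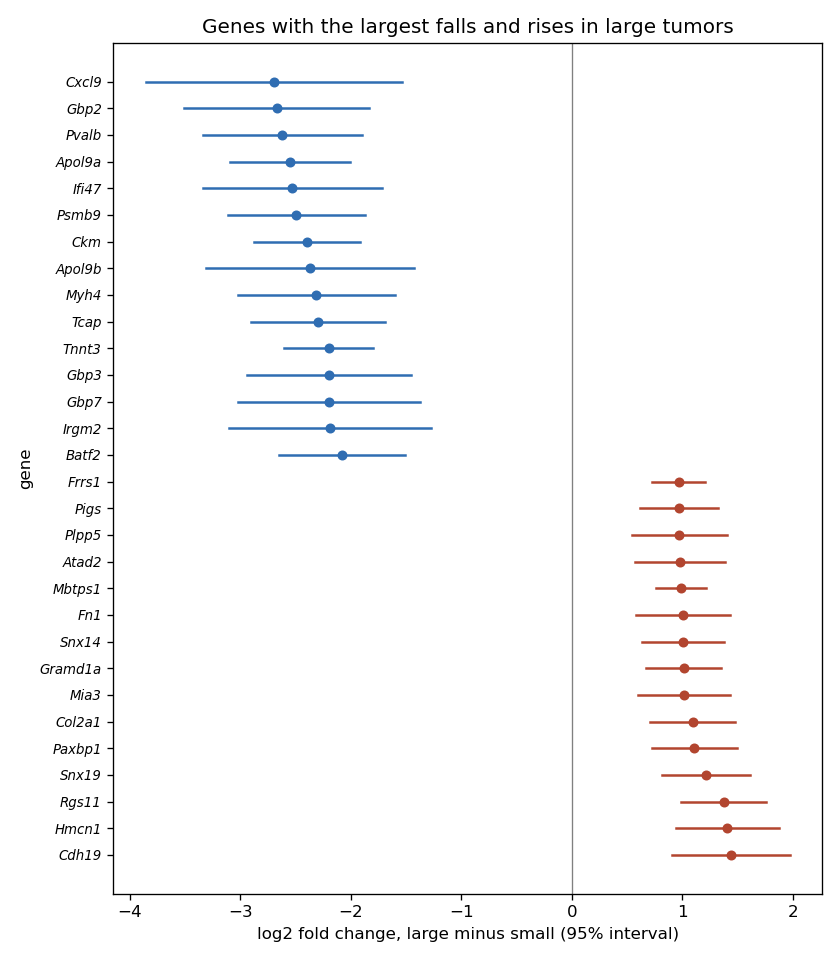
Log2 fold change (large minus small, horizontal axis) of the 15 called genes with the largest fall and the 15 with the largest rise, with points for the fitted value and lines for its 95% interval (3 arrays per group). Falls reach -2.70 for Cxcl9 and rises reach 1.44 for Cdh19.

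After Cdh19, the largest rise among called genes was that of Hmcn1, the matrix protein hemicentin 1, at 1.41 ± 0.20. Its other detected probe went the opposite way at -0.48. Rgs11, a regulator of G protein signalling, rose by 1.37 ± 0.16. Mia3, which loads collagen for export from the endoplasmic reticulum, rose by 1.02 ± 0.18, Mbtps1, the site-1 protease of the Golgi, by 0.99 ± 0.09, and the sorting nexins Snx19 and Snx14 by 1.21 ± 0.17 and 1.01 ± 0.16. Col2a1, a fibrillar collagen of cartilage, rose by 1.09 ± 0.16 and Fn1, fibronectin, by 1.00 ± 0.18. The remaining 6 of the 15 were Paxbp1 (1.11), Gramd1a (1.01), Atad2 (0.98), Plpp5 (0.97), Pigs (0.97) and Frrs1 (0.97), and adjusted p-values of the 15 rises lay between 0.0161 and 0.048.

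Genes induced by interferon-gamma, the main cytokine by which T and NK cells activate other cells, were lower as a group. All 18 tested members had a negative log2 fold change, with a median of -1.97, and 12 fell over all genes tested (18 adjusted over the list alone). Irf1, a transcription factor of the interferon response, fell by 1.87 ± 0.26. The list was lower by camera (adjusted p = 3.45e-16 at the preset correlation of 0.01; adjusted p = 0.295 with an estimated correlation of 0.70). The type I interferon list had a median of -1.15, with 6 of 20 members falling (17 adjusted over the list alone), among them Usp18, a brake on interferon signalling, at -1.40 ± 0.22 and Parp14 at -1.55 ± 0.25. It was also lower by camera (adjusted p = 1.02e-12; adjusted p = 0.295 with an estimated correlation). Without large replicate 1, large replicate 2, large replicate 3 or small replicate 3, 0 members of the interferon-gamma list were called, and without small replicate 2, 5 were. With quantile normalization and no background correction the medians of the interferon-gamma and type I interferon lists were -1.14 and -0.69.

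Antigen presentation genes were lower in large tumors. In the MHC class I list, 10 of 17 members fell and 1 rose (14 and 2 adjusted over the list alone), and the median was -1.15. The immunoproteasome subunits Psmb8 and Psmb10 fell by 1.62 ± 0.13 and 1.30 ± 0.11, and the MHC gene H2-T23 by 1.22 ± 0.16. The member that rose was Calr, the chaperone calreticulin of the endoplasmic reticulum, at 0.75 ± 0.12, named after its value was seen. In the MHC class II list, 8 of 11 members fell (9 lower and 1 higher adjusted over the list alone) and the median was -1.62. H2-DMa, which helps load peptides, fell by 1.97 ± 0.18, H2-Eb1 and H2-Ab1, chains of the presenting molecules, by 1.97 ± 0.21 and 1.80 ± 0.22, and Cd74, the invariant chain, by 1.79 ± 0.22. Both lists were lower by camera (adjusted p = 1.28e-09 and 2.64e-08; adjusted p = 0.295 with an estimated correlation for both). Without large replicate 1, large replicate 3 or small replicate 3, 0 members of either list were called lower, without large replicate 2 there were 2 and 4, and without small replicate 1 there were 10 and 4.

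T cell, NK cell and dendritic cell lists were lower, and B cell and plasma cell markers were not called (camera adjusted p = 0.563, 0 of 5 members called). Of the listed symbols, 14 of 28 were tested for T cells, 7 of 23 for NK cells and 9 of 20 for dendritic cells. For B cells only 5 of 21 were, so the missing call does not show that B cell genes were unchanged. Of 14 T cell markers, 4 fell (7 adjusted over the list alone) and the median was -0.81. Cd3d, a chain of the T cell receptor complex, fell by 1.55 ± 0.21 and Cd6 by 1.47 ± 0.23. Cd2 and Zap70 were not detected in any large tumor and were at least 1.65-fold and 1.51-fold lower. In the list of NK and cytotoxic lymphocyte genes 3 of 7 fell (6 adjusted over the list alone), with a median of -1.13, among them Nkg7, a granule protein, at -1.70 ± 0.24 and Klrd1, an NK receptor chain, at -1.15 ± 0.20. In the dendritic cell list 2 of 9 fell (6 adjusted over the list alone), with a median of -0.99. These were Irf8, a transcription factor of the lineage, at -1.51 ± 0.13 and Siglech, a receptor of plasmacytoid dendritic cells, which was at least 1.91-fold lower. The lists were lower by camera (adjusted p = 2.32e-06, 2.15e-05 and 5.33e-05; adjusted p = 0.286 with an estimated correlation for each). Without large replicate 1, large replicate 2, large replicate 3 or small replicate 3, 0 T cell markers were called. The T cell median was -0.29 with quantile normalization and no background correction, -0.48 with offset 50 and -0.39 when detected on all 6 arrays (adjusted p = 0.0287), and with the muscle covariate added after seeing the data the list was not called (adjusted p = 0.261). There was 1 called T cell marker with the authors' processed values, and 0 with the replicate block. Quantile normalization without background correction gave medians of -0.51 for the NK list and -0.41 for the dendritic cell list.

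Chemokines were lower, with 5 of 24 members falling (13 adjusted over the list alone) and a median of -0.80. Besides Cxcl9 these were Ccl3 at -0.96 ± 0.10, Ccl4 at -1.35 ± 0.17, Ccl8 at -1.25 ± 0.21 and Ccl5 at -1.13 ± 0.19, all attractants of leukocytes. Among checkpoint genes 1 of 16 fell (3 lower and 1 higher adjusted over the list alone), with a median of -0.30. It was Cd274, which encodes PD-L1, at -1.38 ± 0.25 (adjusted p = 0.0466), while Lag3 was at -1.01 ± 0.22 (adjusted p = 0.0689). Both lists were lower by camera (adjusted p = 2.76e-08 and 0.00788; adjusted p = 0.295 and 0.286 with an estimated correlation). Their medians were -0.51 and -0.10 with quantile normalization and no background correction, the first was also -0.51 with every probe on its own, and the second was -0.19 with offset 50.

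The macrophage and suppressive myeloid lists were lower by camera at the preset correlation, with few called members. Of 21 macrophage and monocyte markers 1 fell (2 adjusted over the list alone), Aif1 at -1.60 ± 0.25, and the median was -0.50. Of 12 suppressive myeloid effectors 1 fell (2 adjusted over the list alone), again Cd274, and the median was -0.54. Both were lower by camera (adjusted p = 0.000189 and 0.00992; adjusted p = 0.69 and 0.604 with an estimated correlation), and the second was not called without small replicate 1 (median -0.08, adjusted p = 0.105). The macrophage median was -0.29 without that array. In 2 of the 10 divisions of the arrays into equal groups, the real one included, the macrophage median was as large in size (at most 0.65). The array medians of the macrophage list did not separate the groups, with 0.05 in large replicate 1 and -0.20 in small replicate 2. The median of the suppressive effectors was -0.86 without small replicate 2, -0.19 with quantile normalization and no background correction and -0.34 with offset 50. Neutrophil markers were not called (adjusted p = 0.712), with 0 of 12 members called (1 higher and 1 lower adjusted over the list alone). Their median of -0.24 and mean of 0.16 differed in sign. Some members varied widely within groups, with an SD of 3.76 in large and 4.23 in small tumors for Stfa1 and 3.16 and 2.95 for Asprv1. The array median of the neutrophil list was highest in large replicate 1 (0.68), as was that of the keratinocyte list (2.59). The missing call thus says little about neutrophils. Hdc, which makes histamine, was at -1.28 ± 0.28 and Mmp9, a matrix protease, at 1.12 ± 0.30, the members with the smallest p.

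The interleukin-1 family was not called as a list (adjusted p = 0.82, median -0.28), except lower with the muscle covariate added after seeing the data (median -1.25, adjusted p = 0.014), but 3 of its 12 tested members were called (4 adjusted over the list alone). Il1rap, the accessory chain of the interleukin-1 receptor, rose by 0.64 ± 0.11 (adjusted p = 0.0415), and Sigirr, an inhibitory receptor of the family, rose by 0.80 ± 0.13 (adjusted p = 0.0399). Casp1, the protease that matures interleukin-1 beta, fell by 1.29 ± 0.21 (adjusted p = 0.0399). Of 21 alternatives, Il1rap was called in 6 (log2 fold change 0.21 to 0.69, adjusted p = 0.0241 to 0.94), Sigirr in 13 and Casp1 in 14. Il1b was at -1.19 ± 0.53 (adjusted p = 0.242), the receptor antagonist Il1rn at -0.49 (adjusted p = 0.41), the decoy receptor Il1r2 at -0.57 (adjusted p = 0.166) and the signalling receptor Il1r1 at 0.28 (adjusted p = 0.505). Inflammatory targets of interleukin-1 and NF-kB had a median of -0.31, and 1 of 18 fell (1 adjusted over the list alone), the survival gene Bcl2a1d at -1.56 ± 0.21. Of the 18, 14 were negative and 4 positive. The positive ones, named after their values were seen, were Csf3, Lcn2, Saa3 and Ptges, none of them called. That list was lower by camera (adjusted p = 0.00788; adjusted p = 0.32 with an estimated correlation), and its median was -0.16 with quantile normalization and no background correction.

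Skeletal muscle genes were lower in large tumors, with 17 of 25 falling (23 adjusted over the list alone), all 25 negative and a median of -1.57. Tnnc2, fast troponin C, fell by 1.83 ± 0.17 and Myh1, a fast myosin, by 1.86 ± 0.18. The list was lower by camera (adjusted p = 2.6e-22; adjusted p = 0.286 with an estimated correlation), and 0 members were called without large replicate 1 or large replicate 3, 10 without large replicate 2, 9 without small replicate 1 and 1 without small replicate 3. The array medians of the muscle list separated the groups, as did those of the interferon and antigen presentation lists. With the mean muscle level as a covariate, added after seeing the data, 0 genes were called (limma, 672 at an unadjusted p under 0.05). The T cell list was no longer called by camera (median -0.28, adjusted p = 0.261). The muscle array medians and group were correlated at -0.95, so that model can hardly separate muscle level from tumor size. Its list medians and calls therefore cannot show a difference apart from muscle. The interferon-gamma, MHC class II and MHC class I lists had medians of -2.92, -2.74 and -1.60 in it. They were called lower by camera at the preset correlation (adjusted p = 1.7e-11, 6.56e-13 and 4.14e-07). In all, 13 of the 16 lists stayed called in that model. Among these, the type I interferon, NK, dendritic cell, chemokine and macrophage lists had medians of -3.27, -2.32, -2.22, -2.16 and -2.11. A further 7 lists were gained. These were hypoxia genes (median 0.86, adjusted p = 0.021), glycolysis enzymes (0.91, adjusted p = 0.0186) and nuclear oxidative phosphorylation genes (0.39, adjusted p = 0.0154) as higher, and the interleukin-1 family, neutrophil markers (-1.41, adjusted p = 0.0422), complement genes (-1.14, adjusted p = 0.0407) and fibroblast and matrix genes (-0.73, adjusted p = 0.00264) as lower. Nuclear oxidative phosphorylation genes were not called (adjusted p = 0.82, median 0.03 and mean -0.05), and the 2 of 66 that fell (2 adjusted over the list alone), Cox6a2 at -1.55 ± 0.24 and Cox8b at -1.49 ± 0.24, encode heart and muscle forms of cytochrome oxidase subunits. Adipocyte markers had a median of -0.63 with 0 of 11 called (2 adjusted over the list alone), and were lower by camera (adjusted p = 0.0236; adjusted p = 0.424 with an estimated correlation) but not without large replicate 2 (median -0.38, adjusted p = 0.0626) or small replicate 2 (adjusted p = 0.176). Quantile normalization without background correction gave an adipocyte median of -0.35. The adipocyte call also ended with the authors' processed values (adjusted p = 0.0797), with no detection filter (adjusted p = 0.0501), with the replicate block (adjusted p = 0.0683) and with the muscle covariate (adjusted p = 0.669).

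Lists of tumor cell programs gave few calls. Melanocyte and pigmentation genes were not called (adjusted p = 0.0983, median 0.09), with 0 of 21 called (3 higher adjusted over the list alone), and Kit was at 0.74 ± 0.17 and Gpr143 at 0.56 ± 0.14. The list was called higher with the mean of all detected probes (median 0.31, adjusted p = 0.0059), with every probe on its own (median 0.17, adjusted p = 0.00439) and without small replicate 3 (adjusted p = 0.0491). Melanoma dedifferentiation genes were at a median of -0.07 (adjusted p = 0.375), cell cycle genes at 0.04 (adjusted p = 0.528), hypoxia genes at 0.18 (adjusted p = 0.224), glycolysis enzymes at 0.06 (adjusted p = 0.928), p53 targets at 0.05 (adjusted p = 0.344) and cytosolic ribosomal protein genes at -0.04 (adjusted p = 0.651), with 0 members called in each, also when adjusted over the list alone. Genes of the unfolded protein and integrated stress response were the 1 list that camera at the preset correlation called higher in large tumors, with a median of 0.13 and 0 of 26 called (2 adjusted over the list alone). Camera gave adjusted p = 0.00182, and adjusted p = 0.295 with an estimated correlation. Its median was 0.20 without large replicate 2 or without small replicate 2, 0.22 without small replicate 3, 0.26 with the mean of all detected probes and 0.33 with every probe on its own. In 3 of the 10 divisions of the arrays into 3 and 3, the real one included, its median was as large in size (at most 0.16). Its members with the smallest p were Creld2 at 0.70 ± 0.13 and Sdf2l1 at 0.74 ± 0.15, both of the endoplasmic reticulum. Immediate early and heat shock genes were lower by camera (adjusted p = 0.0156; adjusted p = 0.69 with an estimated correlation), with a median of -0.28 and 0 of 21 called (0 adjusted over the list alone), but not without large replicate 3 (adjusted p = 0.0938) or small replicate 3 (median -0.13, adjusted p = 0.114). Their median was -0.18 without small replicate 1, -0.14 with quantile normalization and no background correction, -0.12 with the mean of all detected probes and -0.11 with every probe on its own. In 2 of the 10 divisions of the arrays, the real one included, their median was as large in size (at most 0.37).

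Lists of stromal, blood and nerve cells gave no camera call with all 6 arrays in the planned model. Fibroblast and matrix genes were at a median of 0.12 (adjusted p = 0.293) with Fn1 as the 1 of 30 that rose (1 adjusted over the list alone), and were called higher without large replicate 3 (adjusted p = 0.0132) or small replicate 3 (adjusted p = 0.038). Matrix proteases and wound genes were at 0.07 (adjusted p = 0.328), with 0 of 18 called (4 adjusted over the list alone) and Mmp10 at 1.43 ± 0.31, and were called higher without large replicate 3 (adjusted p = 0.0109). Endothelial genes were at -0.08 (adjusted p = 0.928), B cell markers at -0.21 (1 member lower adjusted over the list alone) and complement genes at -0.23 (adjusted p = 0.28), the last called lower without small replicate 1 (adjusted p = 0.0283). No member of these 3 lists was called over all genes. Red blood cell genes had a median of 0.01 and mast cell markers of -0.07 (adjusted p = 0.995 and 0.949), and the test's direction was opposite to the median in both, with 0 members called. Schwann cell markers had a median of -0.03 and a mean of 0.14 (adjusted p = 0.813), with 3 members positive and 4 negative and Cdh19 as the 1 of 7 that rose (2 adjusted over the list alone). Fry called this list higher (adjusted p = 0.00739), while camera with an estimated correlation did not call it (adjusted p = 0.89).

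Keratinocyte markers, genes of the skin epithelium, varied widely within both groups. Their median deviation from the mean of the 6 arrays was 2.59, -0.37 and -2.34 in large replicates 1 to 3 and -2.35, 1.27 and 1.79 in small replicates 1 to 3. The list was not called (adjusted p = 0.795, median -0.37, 0 of 23 called and 0 adjusted over the list alone), but it was called lower without large replicate 1 (adjusted p = 0.00505) or small replicate 1 (adjusted p = 0.00255), and with array weights on all 6 arrays (median -1.22, adjusted p = 0.0401). With the mean keratinocyte level as a covariate, added after seeing the data, 287 genes were called, 231 of them among the 260.

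**Figure D2:**
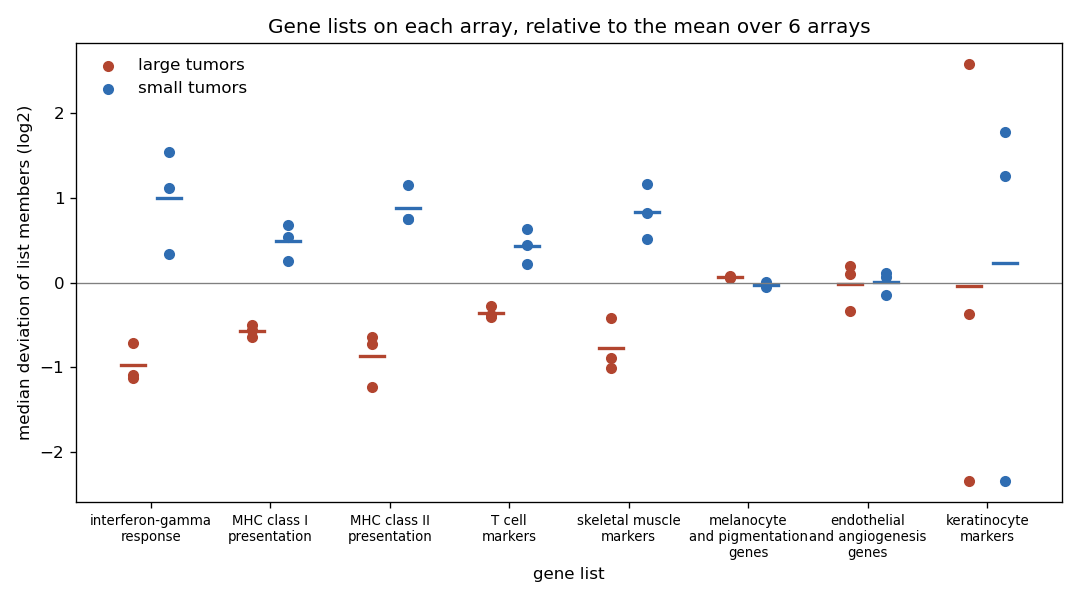
Median deviation of the members of 8 gene lists from their mean over the 6 arrays (vertical axis, log2 scale), for each large and each small tumor, with short lines for group means (3 arrays each). The interferon-gamma list lies between -1.13 and -0.71 in large and between 0.34 and 1.55 in small tumors, while the keratinocyte list spans -2.35 to 2.59 without separating the groups.

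Of the 35 lists, 16 were called by camera, 15 lower and 1 higher in large tumors, and 13 were called by fry, 11 of them by both. Fry also called the melanocyte and Schwann cell lists higher (adjusted p = 0.0444 and 0.00739), which camera with an estimated correlation did not (adjusted p = 0.391 and 0.89). Camera with an estimated correlation called 0 (smallest adjusted p 0.286). The estimate was 0.70 for the interferon-gamma, 0.67 for the type I interferon and 0.76 for the macrophage list. It was 0.50 and 0.53 for the MHC class I and II lists, 0.47 for muscle and 0.06 for T cell markers. Where it lies far above the preset 0.01, p-values at the preset correlation can be far too small. Other divisions of the 6 arrays into 3 and 3 gave 1 to 20 camera calls, so the number of called lists did not set the real division apart. The median of 13 of the 16 called lists was larger in size in the real division than in any other (exact permutation p = 0.1 for each, two-sided, the smallest possible). Their choice by a call in that division favours this. Some share genes, with 6 of 18 interferon-gamma, 6 of 24 chemokine and 4 of 16 checkpoint members in another list. Array medians separated the groups in 12 of the 16. For suppressive myeloid effectors and adipocyte markers, both among the 13, the exact permutation p of the array medians was 0.2 and 0.3.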

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

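The camera tests of lists and the fits with an array left out were planned before the data were examined. Their use here to weigh explanations, and the other tests in this part, were chosen after the results were seen. Among the 2864 detected probes without a single gene symbol, which the comparison of genes did not use, 67 passed an adjusted p of 0.05 in the limma fit over all 19120 detected probes, 25 higher and 42 lower in large tumors. The largest of these changes were -1.93 ± 0.22 for ILMN_2598622 and -1.87 ± 0.36 for ILMN_2925653 on the log2 scale (SE, n = 3 per group).

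Interferon and antigen presentation lists were lower in large tumors by camera at the preset correlation, though not with an estimated one (adjusted p = 0.295). The dim array of small replicate 1 does not account for this, since the interferon-gamma list had a median of -2.26 without it. A lower share of melanoma cells in small tumors would by itself raise the genes of all other cells alike. The 14 T cell genes differed from 63 fibroblast, endothelial and mast cell genes by -0.84 in median (95% bootstrap interval over genes -1.31 to -0.45). This gap separated the groups, at -0.65 to -0.14 in large and 0.21 to 0.82 in small tumors. These genes thus did not move alike on these arrays. The gap cannot decide on the share of melanoma cells, because the T cell list was taken after its fall was seen and the interval resamples genes, not tumors. The interval excluded 0 in 19 of 21 alternatives, with a gap of -0.31 under quantile normalization without background correction, but not for genes detected on all 6 arrays (-0.42, 6 T cell genes) or with the muscle covariate (0.25). Muscle tissue carried over with small tumors cannot be told apart from tumor size here, because muscle level and group were correlated at -0.95 and the group difference of the interferon-gamma list with muscle in the model was -2.90 with an interval of -7.05 to 1.25, and a difference in immune infiltration or interferon signalling with tumor size stays open and was not tested separately.

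The skeletal muscle list was lower in large tumors by camera at the preset correlation (adjusted p = 0.286 with an estimated correlation). The dim array of small replicate 1 does not account for this, as the median was -1.67 without it. Muscle tissue carried over with small tumors is a candidate explanation that was not tested, since what it predicts for this list is the pattern itself. Among the most abundant members, Acta1 was at 13.78 ± 0.09 (SD, n = 3) and Myl1 at 13.35 ± 0.25 on the log2 scale in small tumors, and 1 of the 25 genes is in another list. The labels say that tumors were dissected free of normal tissue, and a difference in muscle contact with tumor size stays open too.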

How the results depend on the processing

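The covariate models were chosen after seeing the data, the other settings before. The 260 called genes (83 higher, 177 lower) became 400 (176 higher) with quantile normalization without background correction, 392 (287 lower) with median scaling, 402 (169 higher) when detected on all 6 arrays, 534 (247 and 287) with every probe on its own, 656 (309 and 347) with an intensity trend and robust prior, 574 (256 and 318) with array weights and 0 (0 higher, 0 lower) with the muscle covariate. With offset 50, 147 were higher. With the replicate block 109 were called, 7 higher and 102 lower. Same-numbered arrays did not deviate together (r = -0.55, -0.07 and -0.45 across genes), which gives no sign that the numbers pair the samples. It cannot exclude pairing, because the arrays varied mainly along 1 axis within groups, which could mask it. Without 1 array the count ran from 0 to 300, with 0 to 77 higher and 0 to 223 lower. All 260 kept their sign in every fit that measured them by gene, except that 230 did with the muscle covariate. For omitted arrays this was fixed in advance, because the groups of these genes did not overlap. The replicate block and the trended prior leave the log2 fold changes unchanged by design. The 16 lists became 0 with an estimated correlation, and 15 to 20 in all other camera settings. The muscle covariate reversed Cd6 (0.16), Cox6a2 (0.53), Cox8b (0.45), Tcap (0.00395) and the fibroblast list (-0.73). It also reversed the camera direction of the oxidative phosphorylation list, whose median was positive in both fits (0.03 and 0.39). Over 133 named genes, 2256 of 2760 values stayed on their side of the threshold, 411 lost and 89 gained a call, and 19 uncalled values changed sign. Over lists these were 702 of 730, 11, 15 and 40. The cause was not tested, except that fewer arrays or fewer genes were used by construction. For 13 of the 260 genes, 1 group had no detected array, so their fold is only a bound. A slide block and settings for Il1a were not run, as no slide was given and no probe was named.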

Other observations

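All tests in this part were chosen after the results were seen. Within groups, the arrays varied mainly along 1 axis, which held 63.1% of the within-group variance, and 67.3% without small replicate 1. The brightest keratinocyte genes varied widely within groups. Krt14, a basal keratin, was at 11.81 ± 3.50 (SD, n = 3) in large and 10.59 ± 5.40 in small tumors on the log2 scale, and Lgals7, an epithelial galectin, at 10.56 ± 2.75 and 11.15 ± 2.77. Of the 23 keratinocyte genes 0 are in another list, and no explanation of this variation was tested.

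Of the 10 divisions of the 6 arrays into 3 and 3, 1 called as many genes as the real one, which is the real one itself, with 260 genes against 112 at most in the other 9. The division with 112 set large replicate 1, small replicate 2 and small replicate 3 against the rest, and the keratinocyte list differed by a median of 3.65 between its sides. For lists, 2 of the 10 divisions called as many as the real one, with 16 in the real division and 20 at most in another. With 10 divisions, a share under 0.05 cannot be reached for either count.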
